A study of Mus musculus with 4 samples.

How the data were processed

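RNA sequencing had been done on 4 libraries of neonatal CD1 mouse cardiomyocytes (postnatal day 1), 1 each for mock transfection and for each of the mimics cel-miR-67, hsa-miR-199a-3p and hsa-miR-590-3p. Mimics were given at 50 nM by reverse transfection and cells were collected after 72 h, per the labels' protocols. Samples were grouped by the treatment named in the labels. Each deposited file gave, per the file headers, a count of total reads and a count of uniquely placed reads for each of 36065 RefSeq transcript records, together with the length of the record and its RPKM. In the deposited values RPKM equals the total reads of a record per kilobase, scaled to the summed reads of the sample, and a column of expression values repeats it. The total count of the authors includes reads shared with other records. Software and genome build are CASAVA 1.8 and mm8, per the submitters' processing notes, which name no role for them. The mapping program is not given in the sources used here. No coordinates are printed, because the reference table of gene names used here belongs to another assembly (GRCm38.p6).

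Current gene symbols were taken from that reference table by transcript accession for 27926 records (77.4%) and from the file headers for the other 8139. Reads of all records of a gene were summed, which gave 27267 genes, 6206 of them with 2 or more records. Libraries held 31638930 (mock), 34255689 (cel-miR-67), 34452240 (hsa-miR-590-3p) and 38745528 (hsa-miR-199a-3p) reads, of which 67.6%, 68.2%, 68.6% and 68.7% were placed uniquely, and 0.812%, 0.375%, 0.637% and 0.369% lay in ribosomal RNA records. At these depths a count of 0 allows up to 0.0987, 0.0897, 0.0849 and 0.0745 CPM (counts scaled to library totals as in edgeR), taking 3 reads as the limit. Reads of records that share sequence with other records (pseudogenes, transcript variants, gene families) may be divided between them in the authors' counting, so the share of uniquely placed reads is given where a named gene with a single record has few of them.

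Counts were scaled by TMM in edgeR 4.0.16 (R 4.3.3), used for its scaling factors only. Log2 ratios of CPM were taken with a prior count of 0.5 for genes with a mean of at least 1 CPM over the 4 libraries, 13502 genes. With 1 library per condition there are 0 residual degrees of freedom, so no test and no p-value was computed, and the 2-fold criterion took each control separately. The mean of both controls served for an alternative of the gene lists and for markers of non-muscle cells, and the summed other 3 libraries for the 2-cell-stage and pluripotent genes. For each microRNA a gene met the criterion when its ratio was at least 2 against cel-miR-67 and at least 2 in the same direction against mock. For cel-miR-67 against mock and for the 2 microRNAs against each other a single ratio of at least 2 was used. Intervals of ratios are exact conditional binomial (Clopper-Pearson) 95% intervals and cover counting error only. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

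The 3 candidate targets are known from the study and are named in no file used here. The criterion, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Named genes were, for each microRNA, the 10 with the highest and the 10 with the lowest ratio against cel-miR-67 among those that met the criterion with at least 50 reads in the higher of those 2 libraries, then up to 2 members per gene list and direction that met it, the most abundant member of a list as an example without such a difference, the 3 candidate targets of the study and the reference genes Gapdh and Actb. For the other comparisons they were the 5 highest and the 5 lowest. A few genes that the rule selects are not reported here. Gene models without an approved-style symbol, pseudogenes, Y-linked genes and Xist were counted but not named. Of 33 gene lists, those with at least 5 measured members were set against random lists, as a description of these libraries. The median log2 ratio of each was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. Leukocyte markers, erythroid markers and the 3 candidate targets had too few measured members and were not placed. A list was called apart when its percentile was at or beyond 2.5 or 97.5 against both controls on the same side.

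Because both microRNAs share their controls, 200 sets of 4 unchanged libraries were drawn, the controls included, around the mean level of both controls. The spread was estimated from mock against cel-miR-67 as if they were a replicate pair, so that it also contains any effect of cel-miR-67. It was a robust spread per bin of expression, which gives little weight to the most different genes. Simulated controls differed at least 2-fold in a mean of 69.4 genes and the real controls in 267, so the simulated counts may be too low. The procedure was tested on simulated data with 200 changed genes. For hsa-miR-590-3p the criterion recovered 2.5% of genes changed 1.5-fold, 31.5% at 2-fold, 96.5% at 3-fold and 99.5% at 4-fold. For hsa-miR-199a-3p it recovered 1.0%, 25.0%, 96.5% and 99.5%, and for either microRNA 0 changed genes went in the wrong direction. In the same runs 8, 14, 14 and 18 unchanged genes met the criterion for hsa-miR-590-3p, and 6, 9, 11 and 9 for hsa-miR-199a-3p. At 1.5-fold these outnumbered the recovered genes, 5 and 2. Of lists drawn at random as a test, 4.6% lay outside the central 95% of their matched random lists, a share set by the way they were drawn. It is not the rate at which a list of genes that vary together would lie apart without a treatment. Several of the real lists lay outside that range between the controls. By its construction the criterion leaves out changes under 2-fold.

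Alternatives were size factors of DESeq2 1.42.0 (used for scaling only), total counts without TMM, no filter on low counts, a minimum mean of 5 CPM, a prior count of 5, uniquely placed reads, the authors' RPKM with a pseudocount of 0.1, each control alone, an interval that excludes 1, and different controls for each microRNA. Added after the data were seen were records not summed per gene, leaving out ribosomal RNA and LOC gene models, thinning to the smallest library, centring within bins of record length, both microRNAs against cel-miR-67, uniquely placed reads for the lists, and random lists matched on length. Seed sites in 3' untranslated regions were to be examined but were not analysed here, since no genome sequence was used here.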

Results

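Gene expression was measured by RNA sequencing in cultured cardiomyocytes of CD1 mice at postnatal day 1, cells of the newborn heart that still contract in culture. Cells received transfection reagent alone (mock), the Caenorhabditis elegans microRNA cel-miR-67 as a control mimic, or the human microRNA mimics hsa-miR-199a-3p or hsa-miR-590-3p, each at 50 nM, and RNA was collected 72 h later. There was 1 library per condition, 4 in all, and the reads assigned to transcripts were 31638930 for mock, 34255689 for cel-miR-67, 34452240 for hsa-miR-590-3p and 38745528 for hsa-miR-199a-3p. After summing transcripts per gene, 13502 genes with a mean of at least 1 CPM (counts scaled to the library total) were compared. Without replicates no significance test was possible, so a difference counted only when a gene was at least 2-fold away from cel-miR-67 and at least 2-fold away from mock in the same direction, and none of the differences has a replicate check. The 95% intervals of ratios cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Log2 ratios are given against cel-miR-67 and then against mock.

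The hsa-miR-590-3p comparison addressed which transcripts differ in cells given this microRNA, which the study examined for its effect on cardiomyocyte proliferation. Genes of the cell cycle were higher than in both controls. All 36 measured genes of mitosis and cytokinesis and all 32 of DNA replication lay above both control libraries, with list medians of 0.68 and 0.88 for mitosis and of 0.52 and 0.65 for replication. Most of these shifts were smaller than 2-fold, and 1 gene of each list met the 2-fold criterion. These were Cenpf, a kinetochore protein, with log2 ratios of 1.17 and 1.31, and Tk1, the thymidine kinase that salvages thymidine for DNA synthesis, with 1.12 and 1.15. The most abundant mitosis gene, Mki67, had 5638 reads under cel-miR-67 and 11006 under hsa-miR-590-3p, with log2 ratios of 0.89 and 0.99, just under the criterion. Among 19 genes of the G1/S transition, with list medians of 0.37 and 0.27, E2f2, a transcription factor of S-phase genes, met the criterion with 1.05 and 1.05, while Ccnd2, a D-type cyclin and the most abundant member, stood at -0.26 and -0.07.

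Sarcomere and oxidative phosphorylation genes were mostly lower under hsa-miR-590-3p, nearly all by less than 2-fold. Of 30 sarcomere genes, 26 lay below both controls, with medians of -0.28 and -0.47, and Myl4, the atrial essential myosin light chain, met the criterion at -1.16 and -1.11. Myh6, the main cardiac myosin heavy chain of the adult mouse, stood at -0.33 and -0.48. Calcium handling and ion channel genes had medians of -0.23 and -0.19, with 15 of 27 members below both controls, and fetal and hypertrophic genes -0.30 and -0.37, with 13 of 18, and with no member of either past 2-fold against both controls. Of 31 genes of oxidative phosphorylation, 28 lay below both controls, with medians of -0.22 and -0.31, and Atp5b, a subunit of ATP synthase, stood at -0.09 and -0.33. Fatty acid oxidation had medians of -0.13 and -0.18, with 16 of 23 genes below both controls, and the unfolded protein and stress response -0.15 and -0.18, with 14 of 23. Glycolysis, at -0.10 and -0.22, did not lie apart from random lists against cel-miR-67. Apart from glycolysis, each of these lists and of the cell-cycle lists above, 9 in all, lay outside the central 95% of 10000 random lists matched on expression, against cel-miR-67 and against mock, which describes these libraries and is not a test of the treatment. Fatty acid oxidation, at percentile 2.42 against cel-miR-67, was at 3.65 with uniquely placed reads and so no longer outside.

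By the fixed criterion 48 genes were higher and 31 lower under hsa-miR-590-3p than in both controls. Gpr27, an orphan G protein-coupled receptor, had the highest ratio against cel-miR-67, 4.73-fold with a 95% counting interval of 2.69 to 8.87, on 75 reads against 15. H1f10, a linker histone listed in the files as H1fx, had log2 ratios of 1.73 and 1.57 on 439 reads against 125, whereas another linker histone, H1f4, listed as Hist1h1e, stood at -1.64 and -1.80. Also high were Dcaf12l2 (1.82 and 1.43), Bex2 (1.82 and 1.11), Shd (1.68 and 1.91), Sapcd2 (1.52 and 1.40), Rtl3 (1.51 and 1.42), Igfbpl1 (ratios of 2.71 and 2.80) and Pcbd1 (1.38 and 1.14). The lowest ratio against cel-miR-67 was that of Edar, the ectodysplasin receptor, at -2.25 and -1.07. Tnnt1, the slow skeletal troponin T, had the lowest ratio to mock among the named genes that met the criterion for this microRNA, -1.36 and -1.87, with 285 reads against 695 under cel-miR-67 and 898 in mock. Lad1 (-1.81 and -1.45), Angptl4, an inhibitor of lipoprotein lipase (-1.61 and -1.51), Cdnf, a neurotrophic factor (ratios of 0.326 and 0.328), and Ccdc63 (-1.45 and -1.49) were also lower. Wnk3 (-1.57 and -1.06), Rps27rt (-1.42 and -1.08) and Xrcc4, a factor of DNA end joining (-1.28 and -1.12), are uncertain, because at most 4.30% of their reads were placed uniquely, and 56.7% of the reads of Bex2 were.

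Libraries simulated without any change, the controls included, gave a mean of 3.58 genes higher and 8.36 lower, at most 13 and 18 over 200 simulations. These counts may be too low, since the simulated controls differed 2-fold in a mean of 69.4 genes and the real controls in 267. Most of the genes were weakly expressed, since a minimum mean of 5 CPM left 18 higher and 13 lower, and the share of higher genes, 60.8%, was 73.6% when libraries were scaled by total counts alone, 73.0% with the authors' RPKM, 71.0% against cel-miR-67 alone and 47.7% for records not summed per gene.

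**Figure D1:**
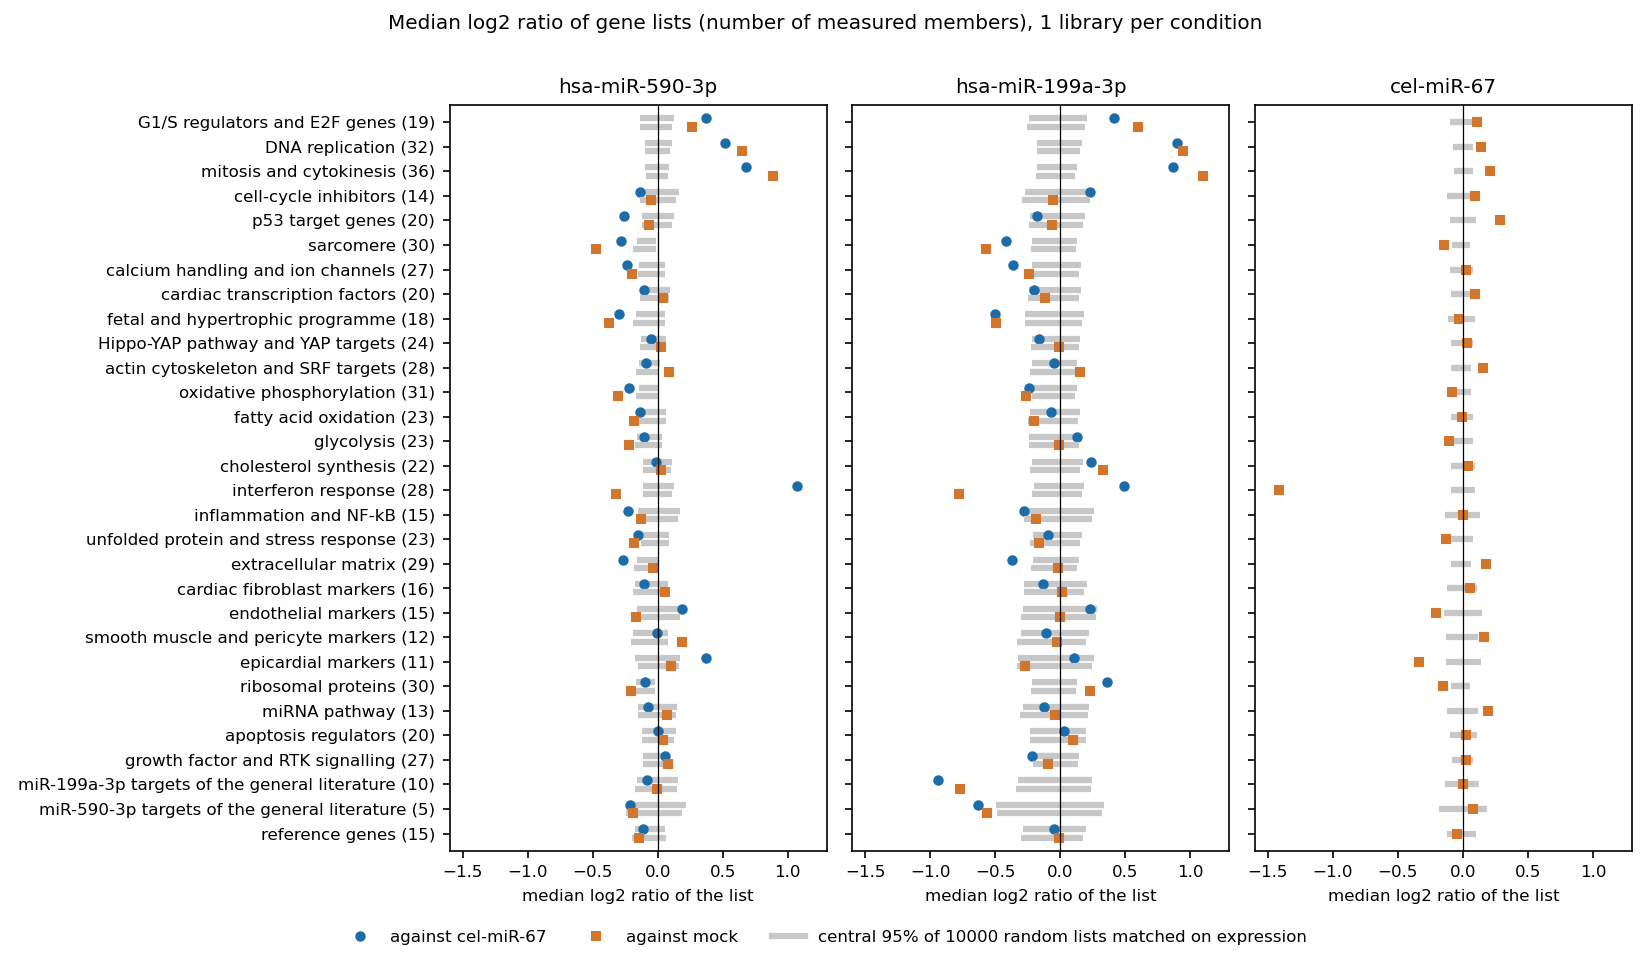
Median log2 ratio of each gene list with at least 5 measured members (horizontal axis, log2 units, the number of members in brackets) for hsa-miR-590-3p (left), hsa-miR-199a-3p (middle) and cel-miR-67 (right), against cel-miR-67 (circles) and against mock (squares), with grey bars for the central 95% of 10000 random lists matched on expression. The mitosis list lies at 0.68 and 0.88 under hsa-miR-590-3p and at 0.87 and 1.10 under hsa-miR-199a-3p, the sarcomere list lies below 0 in all comparisons shown, and the interferon list lies at -1.41 for cel-miR-67 against mock.

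For hsa-miR-199a-3p the same question was asked, and the ratios were more widely spread: the robust SD of log2 ratios over genes was 0.44 against cel-miR-67, compared with 0.27 for hsa-miR-590-3p and 0.22 between the controls. By the criterion 324 genes were higher and 316 lower than in both controls. Cell-cycle genes were again higher, with all 36 mitosis genes and all 32 replication genes above both controls. The mitosis list had medians of 0.87 and 1.10 and 9 members past the criterion, among them Bub1b, a spindle checkpoint kinase (ratios of 2.79 and 3.29), and Birc5, the inhibitor of apoptosis survivin (1.37 and 1.55). Mki67 stood at 0.35 and 0.45. DNA replication had medians of 0.90 and 0.94 and 10 members past the criterion, including Dut, which hydrolyses dUTP (1.49 and 1.33), and Tk1 (ratios of 2.47 and 2.53). In the G1/S list, with medians of 0.42 and 0.60, E2f2 stood at 2.19 and 2.18, a ratio of 4.57 against cel-miR-67 with an interval of 3.64 to 5.78, and Ccne1, cyclin E1, at 1.32 and 1.47. Rb1, the retinoblastoma protein that restrains E2F factors, was lower at -1.63 and -2.10. Of 14 cell-cycle inhibitors, Cdkn2c (1.33 and 1.65) and Cdkn2d (1.00 and 1.05) were higher, although only 5.32% of the reads of Cdkn2d were placed uniquely.

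Sarcomere genes were mostly lower under hsa-miR-199a-3p, with 25 of 30 sarcomere genes below both controls, medians of -0.42 and -0.57, and 5 members past the criterion. Xirp2, an actin-binding protein of the intercalated disc, stood at -1.94 and -3.06, Csrp3, the muscle LIM protein, at -1.86 and -2.12, and Myl4 at -1.51 and -1.46, while Myh6 stood at -0.41 and -0.56. Calcium handling and ion channels had medians of -0.36 and -0.24, with 17 of 27 members below both controls and 5 past the criterion, among them Pln, phospholamban, the regulator of the calcium pump (-1.55 and -1.43), and Kcnj3, a potassium channel (-1.54 and -1.32). In the fetal and hypertrophic list, with medians of -0.50 and -0.49, the natriuretic peptide genes Nppb (-1.64 and -1.75) and Nppa (-1.25 and -1.10) were lower, with 3681 reads of Nppb against 9526 under cel-miR-67. Oxidative phosphorylation had medians of -0.24 and -0.27, and none of its 31 members met the criterion. Among 20 cardiac transcription factors, Hand1 was higher (1.72 and 1.99) and Tbx20, the most abundant, stood at -1.07 and -0.73.

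Cholesterol synthesis genes had medians of 0.24 and 0.33 over 22 members, while 1 member, Hmgcs1, HMG-CoA synthase, was lower at -1.14 and -1.34, a value that rests on reads of which 0.48% were placed uniquely. Ribosomal protein genes had medians of 0.36 and 0.23, with 27 of 30 above both controls and none past 2-fold. In signalling and cytoskeletal lists few members met the criterion. These were Taok1, a kinase upstream of the Hippo pathway (-1.89 and -1.86), Tead4, a transcription factor at its end (ratios of 2.35 and 2.01), Cfl2, muscle cofilin (-1.11 and -1.24), Ago4, an Argonaute protein (-1.25 and -1.40), and Erbb4, a neuregulin receptor (-1.99 and -2.26). In the inflammation list the chemokine genes Ccl7 (-1.74 and -1.86) and Ccl2 (-1.68 and -2.10) were lower, and Atf3, a stress-induced transcription factor, stood at -1.13 and -1.37. Of markers of other heart cells, Postn, a matrix protein of fibroblasts (-2.05 and -1.61), and Rgs5, a pericyte gene (-1.12 and -1.14), were lower and Ednrb, the endothelin B receptor (ratios of 2.06 and 2.85), was higher, while Col1a1, the most abundant fibroblast marker, stood at 0.31 and 0.22.

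Outside the lists, Cd151, a tetraspanin that binds integrins, had the lowest ratio, with 1102 reads under hsa-miR-199a-3p against 11221 under cel-miR-67 and 9826 in mock, log2 ratios of -3.62 and -3.56. Fth1, the heavy chain of ferritin, had 4033 reads against 29934 and 27616 (-3.16 and -3.18), with 64.8% of reads placed uniquely. Nudt12 (-2.71 and -2.60), Steap4, a metalloreductase (-2.42 and -2.52), Il13ra1, a receptor chain for interleukin-13 (-2.38 and -2.22), Wnt7a (-2.31 and -1.36), Pon2, a paraoxonase (-2.27 and -2.49), Otud6b (-2.24 and -2.08) and Serpinb9b (-2.20 and -1.71) were also among the lowest. Pcp4, a calmodulin-binding protein, was the highest, with 1169 reads against 26 and 22, a ratio of 37.3 against cel-miR-67 with an interval of 25.4 to 57.4. Also among the highest were Abcb1a, a drug efflux transporter (4.22 and 3.15), Lypd1 (4.05 and 4.48, 35.8% of reads unique), Car6, a carbonic anhydrase (3.40 and 3.18), Mal (3.34 and 4.47), Lgi3 (3.33 and 2.52), Bcas1 (3.24 and 2.37), Slc1a1, a glutamate transporter (3.07 and 2.86), and Mt3, a metallothionein (3.06 and 2.82). Among 2075 genes with a mean of at least 100 CPM, 5 were higher and 42 lower.

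The lists of mitosis, replication, G1/S, sarcomere, calcium handling, fetal genes, oxidative phosphorylation, cholesterol synthesis and ribosomal proteins lay outside the central 95% of matched random lists against both controls. Unchanged simulated libraries gave means of 2.96 higher and 7.58 lower, which may be too low for the reason given for hsa-miR-590-3p. The share of higher genes, 50.6%, was 63.2% under scaling by total counts, which moved the median of all genes against mock to 0.10, 63.3% with the authors' RPKM and 61.5% without a filter on low counts, but 44.4% for records not summed per gene and 41.5% at a minimum mean of 5 CPM.

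**Figure D2:**
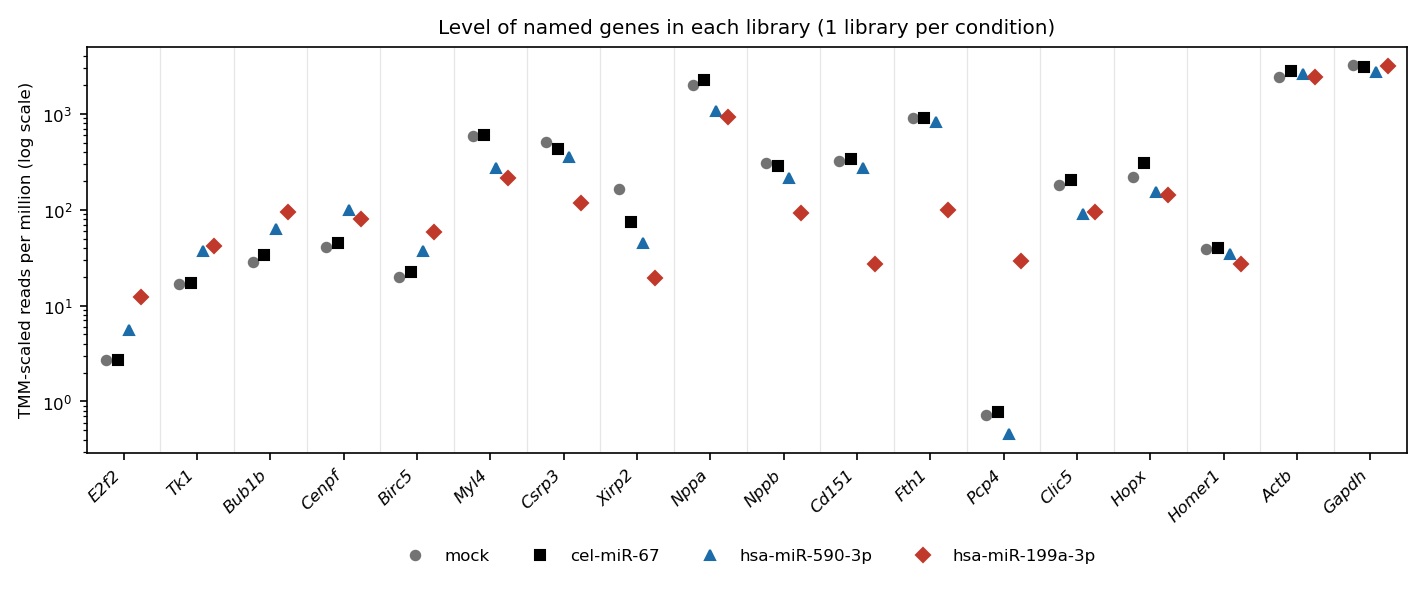
TMM-scaled CPM (vertical axis, log scale) of 18 named genes in each of the 4 libraries, with 1 point per library and no error bars. E2f2, Tk1 and Bub1b lie higher in both microRNA libraries than in both controls, Myl4 lies lower, and Cd151 and Fth1 lie lower in the hsa-miR-199a-3p library alone.

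Genes known, from the study and not from the files, to have been followed up as candidate targets were chosen by the study and so give no independent evidence of direction. They were Homer1, a synaptic and calcium-signalling scaffold, Hopx, a homeodomain-only cofactor, and Clic5, an intracellular chloride channel protein. All 3 lay below both controls in both microRNA libraries. Clic5 met the criterion under hsa-miR-590-3p with ratios of 0.439 and 0.499, and its log2 ratios stood at -1.09 and -0.91 under hsa-miR-199a-3p. Hopx stood at -0.98 and -0.52, and at -1.09 and -0.63. Homer1 stood at -0.22 and -0.19, and at -0.54 and -0.51. When libraries were scaled by total counts, Clic5 under hsa-miR-590-3p stood at -0.91 against mock, short of the criterion. A list of 10 targets of hsa-miR-199a-3p from the general literature had medians of -0.94 and -0.77 under that microRNA, below the random lists, and -0.08 and 0.00 under hsa-miR-590-3p. Taok1 and Ptgs2, cyclooxygenase-2 (-1.39 and -1.85), were its lowest members. The list of 5 targets for hsa-miR-590-3p holds the 3 candidates of the study beside Zeb1 and Zeb2, so it is not independent of them. It had medians of -0.22 and -0.19 under that microRNA, inside the range of random lists, and of -0.64 and -0.56 under hsa-miR-199a-3p, below it. The value of -0.64 is that of Zeb1, which is also a member of the list for hsa-miR-199a-3p. As reference genes, Gapdh stood at -0.18 and -0.23 under hsa-miR-590-3p and within 0.03 of 0 under hsa-miR-199a-3p, where total-count scaling gave 0.12 and 0.10, and Actb stood at -0.12 and 0.10, and at -0.21 and 0.01. Only 2.53% of the reads of Gapdh were placed uniquely.

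Whether both microRNAs acted on the same genes was examined by the overlap of the genes that met the criterion. There were 28 genes higher under both and 11 lower under both, and no gene was higher under one and lower under the other. Those higher included E2f2, Tk1, H1f10, Gpr27, Shd, Sapcd2, Rtl3 and Pcbd1, and those lower Myl4, Lad1, Angptl4, H1f4, Ccdc63 and Xrcc4. Of the members of the gene lists, E2f2, Tk1 and Myl4 met the criterion under both, and no mitosis gene did. Independent lists of these sizes would share 1.15 and 0.73 genes. Unchanged libraries set against the same simulated controls shared means of 0.36 and 0.24, which may also be too low. Across genes, which are not independent replicates, log2 ratios of the 2 microRNAs against cel-miR-67 correlated at r = 0.52, where unchanged libraries gave 0.51, and their covariance was 0.108 against 0.0339. With a different control for each microRNA, r was 0.20 and 0.29, against values near 0 in the simulation. The 2 controls could not be split further, so part of the excess may come from them.

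Compared directly, 366 genes were at least 2-fold higher and 252 at least 2-fold lower under hsa-miR-590-3p than under hsa-miR-199a-3p. Cd151 (log2 ratio 3.32), Fth1 (3.03), Saa3, an acute-phase protein (2.53), and Slc16a12 (2.47) were among the highest, and Pcp4 (-5.96), Mal (-3.85), Lypd1 (-3.73), Avil, an actin regulator (-3.58), and Car6 (-3.05) the lowest. All 30 ribosomal protein genes were lower under hsa-miR-590-3p, with a median of -0.44. The other lists outside the central 95% of matched random lists on the lower side were cell-cycle inhibitors (-0.42), DNA replication (-0.32, 29 of 32 lower), cholesterol synthesis (-0.26, 16 of 22 lower), glycolysis (-0.24), G1/S (-0.20) and mitosis (-0.18). On the higher side they were the literature targets of hsa-miR-199a-3p (0.82), interferon response (0.43), inflammation (0.34), sarcomere (0.23) and growth factor signalling (0.20). Record length moved with this comparison: over genes, the log2 ratio correlated with transcript length at a Spearman coefficient of 0.29, and the median was -0.18 among the shortest 20% of genes and 0.18 among the longest 20%.

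The control comparison asked how far the control mimic itself differed from mock. Under cel-miR-67, 88 genes were at least 2-fold higher and 179 at least 2-fold lower, where unchanged libraries gave a mean total of 69.4, with a spread estimated from this same comparison, so the 2 totals are not independent. All 28 measured interferon-response genes were lower, 18 of them at least 2-fold, with a median of -1.41. Among the lowest ratios were also interferon-induced genes, Zbp1, a nucleic acid sensor (-2.63), Trim30a (-2.38), Trim30d (-2.36) and Tgtp1 (-2.31, 12.8% of reads unique). Ctss, cathepsin S of antigen-presenting cells, was lowest at -3.08. Beside these, leukocyte markers were lower too: 18 such genes had 842 reads in mock and 387 under cel-miR-67, a ratio of 0.418 (interval 0.369 to 0.472), and 336 reads under hsa-miR-590-3p and 450 under hsa-miR-199a-3p. The highest ratios were those of Slc35f1 (1.92), Gria1, a glutamate receptor (1.83), Col19a1 (1.75), Insc (1.75) and Col26a1 (1.61). Some lists that lay apart under a microRNA lay apart between the controls too: mitosis (0.21, 35 of 36 genes higher under cel-miR-67), DNA replication (0.14), G1/S (0.11), sarcomere (-0.15), the unfolded protein and stress response (-0.13) and ribosomal proteins (-0.15, on the other side of 0 from hsa-miR-199a-3p). Calcium handling (0.03), fetal genes (-0.03), oxidative phosphorylation (-0.08), fatty acid oxidation (-0.01) and cholesterol synthesis (0.04) did not. The other lists outside the central 95% of random lists were p53 target genes (0.28), the miRNA pathway (0.20), extracellular matrix (0.18), smooth muscle and pericyte markers (0.16), actin and SRF targets (0.15), cardiac transcription factors (0.10), glycolysis (-0.11), endothelial markers (-0.21) and epicardial markers (-0.34). The direction of the interferon list in the microRNA libraries turned with the control: its median under hsa-miR-590-3p was 1.07 against cel-miR-67 and -0.32 against mock, and under hsa-miR-199a-3p 0.49 and -0.78, so that no member met the criterion.

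**Figure D3:**
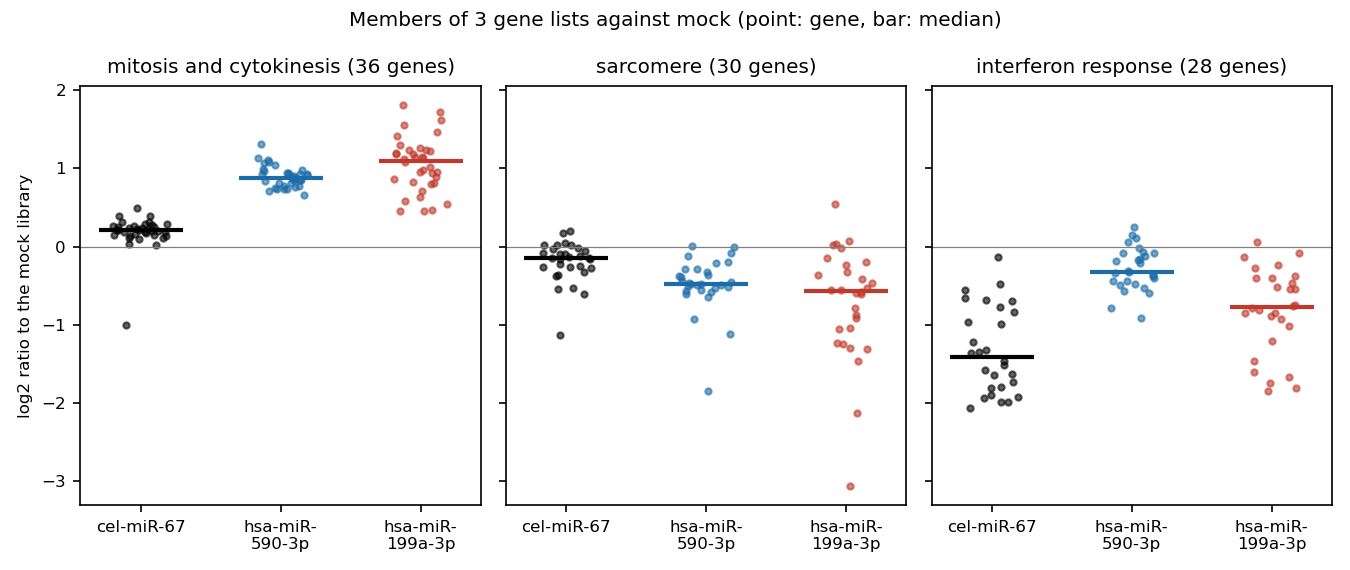
Log2 ratio to the mock library (vertical axis) of each member (points) of the mitosis, sarcomere and interferon lists in the libraries given a mimic, with bars at the medians. The mitosis medians are 0.21 for cel-miR-67, 0.88 for hsa-miR-590-3p and 1.10 for hsa-miR-199a-3p, the sarcomere medians in the same order -0.15, -0.47 and -0.57 and the interferon medians -1.41, -0.32 and -0.78.

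The remaining lists did not lie apart from matched random lists on the same side against both controls. Under hsa-miR-590-3p their medians against cel-miR-67 and mock were -0.14 and -0.05 for cell-cycle inhibitors, -0.26 and -0.06 for p53 target genes, -0.11 and 0.04 for cardiac transcription factors, -0.05 and 0.03 for the Hippo-YAP pathway, -0.09 and 0.08 for actin and SRF targets, -0.10 and -0.22 for glycolysis, -0.02 and 0.02 for cholesterol synthesis, -0.23 and -0.13 for inflammation, -0.27 and -0.04 for extracellular matrix, -0.10 and -0.20 for ribosomal proteins, -0.07 and 0.07 for the miRNA pathway, 0.00 and 0.04 for apoptosis regulators, 0.06 and 0.08 for growth factor signalling and -0.12 and -0.14 for reference genes. Cdkn1a (-0.91 and -0.53) and Ccng1 (-1.51 and -0.91), p53 targets, were below both controls. Markers of other cells had medians of -0.11 and 0.06 for fibroblasts, 0.19 and -0.16 for endothelium, -0.00 and 0.19 for smooth muscle and pericytes and 0.37 and 0.11 for epicardium. Under hsa-miR-199a-3p the medians were 0.23 and -0.05 for cell-cycle inhibitors, -0.18 and -0.06 for p53 target genes, -0.20 and -0.12 for cardiac transcription factors, -0.16 and -0.01 for the Hippo-YAP pathway, -0.05 and 0.15 for actin and SRF targets, -0.07 and -0.20 for fatty acid oxidation, 0.13 and -0.01 for glycolysis, -0.28 and -0.19 for inflammation, -0.10 and -0.16 for the unfolded protein and stress response, -0.37 and -0.02 for extracellular matrix, -0.13 and -0.04 for the miRNA pathway, 0.03 and 0.10 for apoptosis regulators, -0.22 and -0.10 for growth factor signalling and -0.05 and -0.01 for reference genes. For markers of other cells they were -0.13 and 0.01 for fibroblasts, 0.23 and -0.00 for endothelium, -0.11 and -0.03 for smooth muscle and pericytes and 0.10 and -0.27 for epicardium. Of 18 leukocyte markers 4 passed the expression filter, with medians of -0.17 and -0.83 under hsa-miR-590-3p and -0.22 and -0.77 under hsa-miR-199a-3p, and none of 8 erythroid markers did. Total-count scaling, which adds about 0.1 to the ratios of both microRNAs against mock, turned the sign of several of the medians that lie within 0.1 of 0.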

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

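Every test in this part was chosen after the result it bears on had been seen.

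A set of 34 genes known from the mouse 2-cell stage, put together after the data were seen, had 1335 reads under hsa-miR-199a-3p against 182 in mock, 241 under cel-miR-67 and 242 under hsa-miR-590-3p, a ratio of 4.94 to the other 3 libraries (interval 4.501 to 5.434), and of 4.64 with uniquely placed reads only. The 31 of these genes below the expression filter had 840 reads against 33, 86 and 40, a ratio of 13.0 (10.97 to 15.51), with 191 against 2, 21 and 2 for the Zscan4 family and 13 against 0, 0 and 1 for Dux, a transcription factor that activates such genes. Pluripotent cells in that dish as the source are argued against, since 11 markers of such cells had 3 reads there against 15, 13 and 3, a ratio of 0.238 (0.0466 to 0.764). The copies of a single gene family are argued against as well. Of 15 families, some of them single genes with few reads, 11 were higher than in each other library with the lower counting limit of each ratio above 1. Sp110, Zfp352, Arg2 and Gm13043 of the 34 genes were not. Sequence shared between families was not examined by this count. A transcriptional effect of hsa-miR-199a-3p on these genes may stay open as a hypothesis, in 1 library. Total reads of the 31 genes were also higher under cel-miR-67, at 2.37 (1.57 to 3.65) times mock. All 34 genes stood there at 1.20 (0.988 to 1.47) times mock, but at 0.868 (0.660 to 1.14) with uniquely placed reads. Whether higher reads were confined to the hsa-miR-199a-3p library is therefore not settled.

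Ribosomal protein genes differed between the microRNAs: 27 of 30 lay above both controls under hsa-miR-199a-3p and 24 of 30 below both under hsa-miR-590-3p, with a median of -0.44 for hsa-miR-590-3p against hsa-miR-199a-3p. The difference was not tested, and centring by record length lowered the median under hsa-miR-199a-3p against cel-miR-67 from 0.36 to 0.24. Under hsa-miR-590-3p the list median against cel-miR-67 was -0.097, inside the matched random range of -0.165 to -0.019. Against mock it was -0.2032, just below a range of -0.1995 to -0.0242. Both ranges lie below 0, so the count of 24 alone does not set these genes apart. The shortest genes also had medians below 0 under hsa-miR-590-3p (-0.066 against cel-miR-67, -0.107 against mock). Centring of this list was not examined there.

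Interferon-response genes were lowest in the cel-miR-67 library, 1 of the 2 controls, with a median of -1.41 against mock. Summed leukocyte markers in hsa-miR-590-3p were 0.822 of those in cel-miR-67 (0.708 to 0.953), although its interferon median was higher by 1.07. For the summed markers this argues against leukocytes lost from the cel-miR-67 dish alone as the whole cause. Single macrophage genes do not decide it. Ctss, Tyrobp and Adgre1 had ratios of 1.69 (0.939 to 3.14), 2.21 (0.504 to 13.2) and 1.62 (0.589 to 4.86). Lyz2 had 0.588 (0.448 to 0.768) and C1qa 0.946 (0.127 to 7.06). The lower leukocyte markers in all 3 mimic libraries than in mock may still carry part of the difference from mock. An effect of the mimic, or of the single cel-miR-67 culture, on interferon genes remains open and was not tested.

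Cell-cycle lists were higher under both microRNAs than in both controls, and the controls differed as well, with a mitosis median of 0.21 for cel-miR-67 against mock. Markers of fibroblast, endothelial, smooth muscle and epicardial cells, 51 in all, were pooled and compared with the mean of both controls. Their median was 0.0469 (bootstrap interval over genes -0.01 to 0.08) under hsa-miR-590-3p and 0.0183 (-0.18 to 0.14) under hsa-miR-199a-3p. Mitosis genes had 0.76 and 1.01. These values argue against an even rise of all these cell kinds as the whole cause. A rise of a single kind could be hidden in the pooled median. Under hsa-miR-590-3p epicardial markers stood at 0.37 and 0.11 and fibroblast markers at -0.11 and 0.06. A change in the balance of muscle and other cells is not settled, since sarcomere genes were lower under both microRNAs. The length trend of the hsa-miR-199a-3p library is argued against too, since the mitosis median was 0.86 after centring by length and 0.87 before. These values are consistent with more cycling cells under both microRNAs as a hypothesis, found and tested on the same 4 libraries. Which cell type carries the transcripts stays open, as bulk RNA does not separate cardiomyocytes from other cells of the culture, and a difference between single cultures was not tested.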

How the results depend on the processing

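Records not summed per gene, leaving out ribosomal RNA and LOC gene models, thinning, centring by record length, both microRNAs against cel-miR-67, uniquely placed reads for lists and random lists matched on length were chosen after the data had been seen. No paired analysis was possible because there was 1 library per condition and the labels give no replicate numbers. Alternatives on seed sites in 3' untranslated regions were not run, since no genome sequence was used here. Of the values of the gene counts and the correlation under an alternative, 87 stayed within 1.5 times the reported value, or within its spread, and 47 did not. No named gene at least 2-fold away changed direction, 1260 values stayed within the counting interval of the ratio and 223 moved beyond it. The 1260 include values without a filter and at a minimum mean of 5 CPM, where the ratio of a gene cannot change by construction. Of the values of lists that lay apart from random lists against both controls, 119 kept that place. Those with mock as the control could not do otherwise, since both controls had been used to select these lists. Fatty acid oxidation under hsa-miR-590-3p lost its place, with a median of -0.13 at percentile 3.65 with uniquely placed reads. The cause was not tested.

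Without a filter, which admits genes of few reads, 886 genes were higher and 653 lower under hsa-miR-590-3p, 1631 and 1023 under hsa-miR-199a-3p, 1739 and 1626 under cel-miR-67 against mock, 1834 and 2305 for hsa-miR-590-3p against hsa-miR-199a-3p, and 358 and 218 under both microRNAs. A minimum mean of 5 CPM, which tests fewer genes, gave 18 and 13 for hsa-miR-590-3p, 167 and 235 for hsa-miR-199a-3p, 41 and 87 for cel-miR-67 against mock, 250 and 105 for hsa-miR-590-3p against hsa-miR-199a-3p, and 14 and 4 under both. With the authors' RPKM, which lacks the TMM factor and had a pseudocount of 0.1, 46 genes were higher and 17 lower under hsa-miR-590-3p and 362 and 210 under hsa-miR-199a-3p, where total counts gave 64 and 23, and 413 and 240. Records not summed per gene gave 133 and 146 for hsa-miR-590-3p, 422 and 529 for hsa-miR-199a-3p, 356 and 445 for cel-miR-67 against mock, 735 and 527 for hsa-miR-590-3p against hsa-miR-199a-3p, and 53 and 32 under both, in records, some of which share their reads.

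A criterion against 1 control admits more genes by construction: against cel-miR-67 alone 225 and 92 for hsa-miR-590-3p and 537 and 495 for hsa-miR-199a-3p, and against mock alone 156 and 92, and 534 and 504. Genes higher and lower under both microRNAs then numbered 98 and 43 against mock, 123 and 31 against cel-miR-67, 56 and 18 with hsa-miR-590-3p against cel-miR-67 and hsa-miR-199a-3p against mock, and 59 and 20 the other way round, with correlations of 0.20 and 0.29 for those crossed controls. The list medians that passed from outside the random lists on one side to outside on the other did so with mock as the control: interferon response under hsa-miR-590-3p (-0.32) and hsa-miR-199a-3p (-0.78), and endothelial markers under hsa-miR-590-3p (-0.16), as these lists were lower in cel-miR-67 than in mock. Medians nearer to the random lists also changed sign with mock, such as epicardial markers under hsa-miR-199a-3p (0.10 and -0.27). An interval that excludes 1 removed no gene from either microRNA's counts. It covers counting error only, and at the read counts above the filter a 2-fold difference could seldom have failed it. These counts are among the 87 values that stayed. Thinned to the smallest library, hsa-miR-590-3p had 47 higher and 33 lower and hsa-miR-199a-3p 316 and 327, so depth differences between libraries moved these counts little.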

Other observations

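Genes of this part were singled out after their values had been seen, and no explanation was tested here.

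Markers of macrophages were lower in each of the 3 mimic libraries than in mock, by unequal amounts. Ctss, cathepsin S, had 149 reads in mock, 19 under cel-miR-67, 34 under hsa-miR-590-3p and 22 under hsa-miR-199a-3p. Lyz2, a lysozyme of myeloid cells, had 349, 148, 92 and 174, and C1qa, a complement component made by macrophages, 29, 3, 3 and 12. Tyrobp, a signalling adapter of myeloid receptors, had 22, 3, 7 and 7, and Adgre1, the F4/80 antigen, 35, 7, 12 and 3. The summed reads of the 18 leukocyte markers were 842, 387, 336 and 450. Of the 4 that passed the expression filter, Lyz2 and Cd68 had log2 ratios of -1.37 and -1.15 for cel-miR-67 against mock. The other members, Csf1r and Cd14, stood at only -0.20 and -0.14.

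Under hsa-miR-199a-3p the balance of higher and lower genes moved with expression. Of all 13502 genes 324 were higher and 316 lower, of 9589 genes with a mean of at least 10 CPM 116 and 195, of 4190 with at least 50 CPM 19 and 87, and of 2075 with at least 100 CPM 5 and 42. Under hsa-miR-590-3p the counts in the last group were 0 and 3.

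The summed count of Homer1 hid a difference between its transcript records. The record of variant L had 22 reads in mock, 98 under cel-miR-67, 314 under hsa-miR-590-3p and 92 under hsa-miR-199a-3p, that of variant d 719, 691, 506 and 634, and that of variant S 442, 538, 388 and 374. Almost all of these reads were shared between records, with 0, 2, 9 and 3 uniquely placed reads for variant L, so the division between variants is uncertain.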
